A study of Mus musculus with 10 samples.

How the data were processed

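The study measured gene expression in CD4+ cells from the spleens of mice that lack Il1rn, the gene of the interleukin-1 receptor antagonist, and of wild-type mice, at 1 and 4 months of age. Each array came from a separate mouse, per the design text of the series, and each of the 10 mice gave 1 Affymetrix array with 45101 probe sets. Knockout mice numbered 2 at each age and wild-type mice 3. Total RNA was extracted with Trizol and labelled with biotin under the standard protocol of the array maker, per the labels. The labels give no strain, sex, purity of the sort, disease state of the single mice, array date or batch, and no detection calls were used here.

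The deposited values were intensity signals on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; the settings of that step are not given in the sources used here. Every deposited array already had a mean intensity of 500 after 2% of the probe sets was trimmed from each end, so scaling to that target left the arrays as deposited. Such scaling sets the bright part of each array to a common level and leaves the dim part free to differ. Medians of the arrays ran from 65.2 to 109.

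Values were turned into log2(intensity + 16), which understates the change of dim genes. Of the 45101 probe sets, 34958 had a single gene symbol in the platform annotation, 932 had several, and 9211 were unnamed; 64 of the 45101 were controls of the array maker. Symbols were checked by gene identifier against the RefSeq gene table of assembly GRCm38.p6, where 34754 probe sets had a match and 0 symbols needed an update; that table was used for names and for which genes neighbour each other. A probe set was kept when it lay above the median of its array in at least 2 of the 10 arrays, which left 26277 probe sets. Each gene was represented by its kept probe set of highest mean, taking one that can bind several transcripts only where the gene had no other, which gave 11759 of 18194 genes. Unnamed probe sets and those with several genes stayed out of the gene tests.

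The main test was limma 3.58.1 in R 4.3.3 on the means of the 4 groups, with empirical Bayes moderation along an intensity trend (6 residual and 6.06 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of 0.05. All 10 arrays entered every fit, so that the groups shared 1 estimate of the spread. The 6 contrasts were knockout against wild type at 1 month, at 4 months and in the mean of both ages, 4 against 1 month in each genotype, and the interaction. An exact test of 2 against 3 arrays cannot give a p under 0.1, and the number of arrays limits the precision of every value. Where no gene differs, 588 of the 11759 genes are expected to have an unadjusted p under 0.05. Changes are given in log2 with the standard error of limma, which is written after the sign ±.

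Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, over lists with at least 5 measured genes, adjusted over the 29 lists that met this. They covered the IL-1 family, Th1, Th2, Th17, Treg, Tfh, naive and effector memory T cells, T cell receptor signalling, immediate early genes, NF-kB, interferon response, proliferation, heat shock, glycolysis, oxidative phosphorylation, ribosomal proteins, chemokine receptors, bone and joint mediators, and markers of B cells, plasma cells, CD8 T and NK cells, macrophages, granulocytes, erythroid cells, platelets, dendritic cells, mast cells and stroma. A list of sex-linked genes was fixed as well. The groups, contrasts, tests, lists, alternatives and the rule for naming genes were set before the data were examined.

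Named genes were the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, filled to 5 per direction with genes of at least a 2-fold difference that did not pass, and the 4 members of smallest p of each list described. For the mean of both ages the groups had to be separate at both ages. Symbols that are only clone or sequence names were left out of the ranking. Every named gene that passed therefore differed in the stated direction in all arrays of the groups compared. Exceptions are list members, genes said to lie outside the rule and those of the interaction, where separate groups were not required.

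The alternatives tried were quantile normalization, values as deposited, pseudocounts of 1 and 64, no filter, a filter at percentile 75, no intensity trend, array weights, only the groups compared, the mean of a gene's probe sets, every probe set, the replicate number as a block, each array left out in turn, an estimated correlation and fry for the lists. Marker scores of granulocytes and B cells as covariates were added after the data were seen. So was a fit without knockout array 1 and wild-type array 1 of 1 month. Each fit that left out arrays repeated the filter and the choice of a probe set for each gene. Tested on simulated data with 11759 genes, the fit for knockout against wild type at 4 months recovered 46.3% of changes of log2 1, 89.6% of 2 and 98.5% of 3, with 10 unchanged genes called. For 4 against 1 month in wild type it recovered 65.7%, 91.0% and 100%, with 4 unchanged genes called. In each simulation 67, 67 and 66 genes changed by log2 1, 2 and 3, with the change added to the log2 value. The noise was drawn independently for each gene, whereas granulocyte and B cell markers varied together in the real arrays. These shares therefore describe the simulated setting and are not the power of the real comparisons.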

Results

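CD4+ cells from mouse spleen were profiled on 10 arrays, from 2 knockout and 3 wild-type mice at 1 month and again at 4 months of age. Il1rn encodes an antagonist that keeps interleukin-1 from its receptor, and the series concerns arthritis in mice. The arrays of a group correlated at 0.954 to 0.978 across genes, and arrays of different groups at 0.891 to 0.972. The first principal component held 48.0% of the variance and separated the ages, from -56.1 to -12.5 at 1 month and from 17.5 to 40.0 at 4 months. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.13 to 1.40 for beta-actin and 1.99 to 4.39 for the transferrin receptor. At 1 month, wild-type array 3 had the highest of both (1.40 and 4.39), and knockout array 1 read 1.38 for beta-actin. For Gapdh the ratio separated the ages, at 0.693 to 0.765 at 1 month and 0.614 to 0.665 at 4 months. Array medians were 65.2 to 84.6 at 1 month, lowest in knockout array 1, and 98.6 to 109 at 4 months. The control probe set for B1 repeats read 3035 to 4958 at 1 month and 8343 to 10772 at 4 months. The Y-linked Eif2s3y read 1840 to 3280 on its brighter probe set, and the 3 Xist probe sets reached at most 314. The sex-linked list held 4 measured genes, under the minimum of 5, and was not tested.

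The targeted gene was near the floor of the arrays. Il1rn had 3 probe sets, which lay above the array median in at most 1 array. The first averaged 22.8 ± 13.9 intensity units in the knockout (SD, n = 4) and 52.5 ± 8.7 in wild type (SD, n = 6). In limma its log2 difference was -0.90 ± 0.32 in the mean of both ages, which did not pass (adjusted p = 0.656, unadjusted p = 0.0146). The knockout arrays read 2.8 to 33.2 on this probe set, all below the 38.4 to 60.8 of wild type. On the other probe sets the genotypes overlapped. Another averaged 22.4 ± 12.8 and 39.5 ± 46.5, and the brightest averaged 56.8 ± 11.7 and 62.6 ± 30.3 in knockout and wild type (SD). Where the probes lie relative to the deleted part is not given in the sources used here, so these values did not check the labels. The IL-1 family list, with 15 measured members, had a median of 0.04 at 1 month (camera adjusted p = 0.537) and 0.13 at 4 months (adjusted p = 0.405), and its Il1r1 differed by 0.56 ± 0.50 and 1.04 ± 0.50 without passing.

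At 1 month, the question was which genes of CD4+ cells differ in the absence of the antagonist. Of 11759 genes, 3 were higher and 6 lower in the knockout. Arl2bp, which encodes a binding partner of the small GTPase ARL2, rose by 3.19 ± 0.23, or 9.16-fold (adjusted p = 8.97e-05), and its other probe set differed by 3.13. Ms4a3, a gene of granulocyte precursors, rose by 2.12 ± 0.31 and Plac8 by 1.11 ± 0.17 (adjusted p = 0.0288 for both). Oas1b and Oas1a, genes of the interferon-induced oligoadenylate synthetase family, changed by -2.90 ± 0.34 (adjusted p = 0.00982) and -3.30 ± 0.49 (adjusted p = 0.0288). Oas1b was near the floor in the knockout, so the size depends on the pseudocount, with -3.78 at 1 and -1.84 at 64; Oas1a did not pass with a pseudocount of 1 or quantile normalization. Ctps2, a CTP synthase, changed by -2.39 ± 0.31 and Dnah8, an axonemal dynein, by -1.66 ± 0.22 (adjusted p = 0.0186 for both). The pseudogene Pisd-ps3 changed by -1.49 ± 0.21 (adjusted p = 0.0268). The immunoglobulin gene Ighg3 changed by -3.07 ± 0.42 (adjusted p = 0.0222), while its 2 other probe sets differed by 0.46 and 0.96. Alox5ap (1.89 ± 0.31, adjusted p = 0.0561) and Anxa3 (1.68 ± 0.29, adjusted p = 0.0826) did not pass. Of the 10 fits that left out 1 array, Arl2bp passed in 10, Oas1b, Ctps2, Dnah8 and Ighg3 in 7, Pisd-ps3 in 5, Ms4a3 and Oas1a in 4 and Plac8 in 3. The 9 genes became 3 without knockout array 1 of that age, 1 without wild-type array 2, 1 without wild-type array 3 and 5 without 4-month wild-type array 3. With array weights 3 genes passed, and with the granulocyte score as a covariate, added after the data were seen, 1 passed.

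Markers of myeloid cells were the lists that stood furthest apart at 1 month. Of 25 granulocyte genes, 1 rose (Ms4a3) and 24 did not pass limma's test, 24 of the 25 were positive, and 16 were higher when adjusted over the list alone. Mmp8 differed by 2.83 ± 0.67, Hp by 2.54 ± 0.59 and the neutrophil protease Ctsg by 2.09 ± 0.47 (adjusted p = 0.296, 0.291 and 0.291). The median was 2.09, or 4.25-fold (camera adjusted p = 4.5e-15; adjusted p = 0.46 with an estimated correlation). The neutrophil gene S100a8 read 19550 and 32102 in the 2 knockout arrays and 17484, 1361 and 2966 in the 3 wild-type arrays. Of 23 macrophage genes, 10 had an unadjusted p under 0.05 and 6 were higher when adjusted over the list alone, with a median of 0.90 (camera adjusted p = 5.72e-10) and with Tyrobp at 1.76 ± 0.38. Mast cell markers had a median of 0.56 and 3 of 9 higher when adjusted over the list alone (camera adjusted p = 0.00385). Both had an adjusted p = 0.46 with an estimated correlation.

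Several lists of T cell genes lay lower in the knockout at 1 month, calls that rested on knockout array 1 of that age. T cell receptor signalling had a median of -0.37 with 26 of 27 genes negative (camera adjusted p = 1.37e-05), and naive T cell genes -0.43 with 18 of 18 negative (adjusted p = 5.03e-05). Both had an adjusted p = 0.46 with an estimated correlation. Medians were -0.40 for Treg, -0.37 for Tfh, -0.23 for NF-kB and -0.44 for immediate early genes (adjusted p = 0.46 with an estimated correlation). Of 34 interferon response genes, 1 fell (Oas1a), 33 did not pass and the median was -0.31 (camera adjusted p = 0.000197; adjusted p = 0.46 with an estimated correlation). Camera did not call effector memory (median 0.01, 16 of 29 genes positive), Th1 (-0.09), Th2 (-0.32) or Th17 genes (-0.30), with adjusted p = 0.809, 0.312, 0.447 and 0.101. Members of these lists were Traf1 at -0.94 ± 0.21, Jund at -0.97 ± 0.25, Bach2 at -0.75 ± 0.23 and Maf at -0.67 ± 0.18, none past the test (adjusted p = 0.291, 0.409, 0.5 and 0.424). Higher medians were found for oxidative phosphorylation (0.22, 47 of 49 positive, adjusted p = 1.51e-09), proliferation (0.32, 34 of 37 positive, adjusted p = 4.83e-06), ribosomal proteins (0.16), heat shock (0.15) and erythroid genes (0.24), with an adjusted p = 0.46 to 0.68 with an estimated correlation. When adjusted over the list alone, 6 effector memory genes (3 higher, 3 lower), 2 NF-kB genes and 1 gene each of the interferon, Tfh, Th17, B cell and dendritic cell lists passed. With an estimated correlation, 0 of the 15 lists called by camera held, 2 lists had an unadjusted p under 0.05, and fry called 0 with 3 at an unadjusted p under 0.05. Without knockout array 1 of that age camera called 8 lists, 8 higher and 0 lower, so none of the 7 lower calls held. The list means, without passing, then became 0.00 for T cell receptor, -0.07 for naive, -0.05 for Treg, -0.06 for Tfh, 0.02 for NF-kB, 0.00 for immediate early, -0.17 for interferon response and -0.08 for erythroid genes (adjusted p = 0.45 to 0.838). Without knockout array 2 the mean of the ribosomal list became -0.02.

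At 4 months, 4 genes were higher and 6 lower in the knockout. Hspa1b, an inducible heat shock protein 70, rose by 3.64 ± 0.35, or 12.4-fold, from near the floor in wild type (adjusted p = 0.00059), and its 2 other probe sets differed by 3.53 and 3.71. Cxcr4, the receptor of the chemokine CXCL12, rose by 2.36 ± 0.22 (adjusted p = 0.00059), Arl2bp by 2.74 ± 0.23 (adjusted p = 0.000516) and Clec2d, a ligand of an NK cell receptor, by 2.40 ± 0.37 (adjusted p = 0.0436). Oas1b changed by -3.60 ± 0.34 (adjusted p = 0.00059), to near the floor in the knockout, with -4.58 at a pseudocount of 1 and -2.42 at 64. In the same direction went Ctps2 by -2.61 ± 0.31 (adjusted p = 0.00514) and Sfi1 by -2.28 ± 0.32 (adjusted p = 0.0186). Mpeg1, a pore-forming protein of macrophages, changed by -3.04 ± 0.49 (adjusted p = 0.0478), to near the floor in the knockout, with -3.53 at a pseudocount of 1 and -2.20 at 64. The cold-induced RNA-binding protein Cirbp changed by -1.24 ± 0.19 (adjusted p = 0.0436) and the glyoxalase Glo1 by -1.17 ± 0.15 (adjusted p = 0.00774). Tsc22d3, a glucocorticoid-induced gene, differed by 1.21 without passing (adjusted p = 0.0999). Hspa1b, Arl2bp, Cxcr4 and Oas1b passed in each of the 10 fits that left out 1 array, Ctps2 in 9, Glo1 in 8, Sfi1 in 6, Clec2d and Cirbp in 4 and Mpeg1 in 2. The 10 genes became 4 without knockout array 1 of that age, 5 without knockout array 2 and 6 without wild-type array 1. Array weights gave 192 genes, a fit of the compared groups alone 74, and a fit without knockout array 1 and wild-type array 1 of 1 month 29.

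B cell markers lay lower in the knockout at 4 months. All 21 were negative with a median of -1.30 (camera adjusted p = 1.59e-10; adjusted p = 0.58 with an estimated correlation), 13 had an unadjusted p under 0.05 in limma and 11 were lower when adjusted over the list alone. Ms4a1, which encodes CD20, differed by -1.90 ± 0.41 and the class II gene H2-Aa by -2.38 ± 0.55 (adjusted p = 0.197 and 0.252). Of 15 CD8 T and NK cell genes, 6 were lower when adjusted over the list alone and the median was -0.87 (camera adjusted p = 2.81e-06; adjusted p = 0.55 with an estimated correlation). Cd8a read 31 and 245 in the knockout arrays against 465, 965 and 528 in wild type. Th1 genes had a median of -0.50, with 4 of 15 lower when adjusted over the list alone (adjusted p = 0.00106; adjusted p = 0.61 with an estimated correlation), led by Ccl5 at -1.59 ± 0.33 and Gzmb at -1.67 ± 0.36, neither past the test (adjusted p = 0.165 and 0.182).

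Of 26 heat shock genes, 1 rose (Hspa1b), 25 did not pass and 6 were higher when adjusted over the list alone, with a median of 0.21 (camera adjusted p = 2.74e-05; adjusted p = 0.55 with an estimated correlation). The co-chaperone Dnaja1 differed by 0.89 ± 0.16 and Hsph1 by 1.15 ± 0.22 (adjusted p = 0.0955 and 0.114). Of 23 macrophage genes, 1 fell (Mpeg1), 2 were lower when adjusted over the list alone and the median was -0.60 (camera adjusted p = 0.000128; adjusted p = 0.63 with an estimated correlation). Medians were -0.41 for proliferation, -0.57 for erythroid, -0.46 for mast cell, -0.14 for effector memory and -0.17 for dendritic cell genes, and 0.10 for ribosomal, 0.17 for plasma cell, 0.15 for T cell receptor, 0.12 for Tfh and 0.33 for granulocyte genes, all called by camera and with an adjusted p = 0.55 to 0.76 with an estimated correlation. Over all alternatives to the main setting, the dendritic cell list kept its call in 6 of 19 and the granulocyte list in 4 of 17. With 1 array left out in turn the mean ranged from -0.53 to -0.20 for proliferation (from -0.39) and from -0.82 to -0.33 for erythroid genes (from -0.58). Without knockout array 2 of that age the mean of the granulocyte list became -0.18, that of T cell receptor genes 0.03 (from 0.12) and that of Tfh genes 0.03 (from 0.18). Without knockout array 1 the mean of effector memory genes became -0.05 (from -0.22) and that of ribosomal genes 0.03 (from 0.09), and without wild-type array 1 that of plasma cell genes 0.09 (from 0.30). None of these 6 lists passed in the fit named. Of the lists called, 3 mast cell genes, 1 effector memory gene and 1 plasma cell gene passed when adjusted over the list alone; of those not called, 3 immediate early, 2 Treg and 2 platelet genes and 1 gene each of the interferon, chemokine receptor and bone and joint lists did. With an estimated correlation 0 of the 15 lists held, 2 lists had an unadjusted p under 0.05, and fry called 0 with 4 at an unadjusted p under 0.05.

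In the mean of both ages, 4 knockout against 6 wild-type mice, 3 genes were higher and 10 lower. Arl2bp rose by 2.97 ± 0.16 (adjusted p = 3.86e-06), Hspa1b by 2.26 ± 0.24 and Cxcr4 by 1.45 ± 0.16 (adjusted p = 0.00188 for both). Oas1b changed by -3.25 ± 0.24 (adjusted p = 6.23e-05; -4.18 and -2.13 at pseudocounts of 1 and 64), Oas1a by -2.90 ± 0.35 (adjusted p = 0.00275) and Ctps2 by -2.50 ± 0.22 (adjusted p = 0.000326). Sfi1 (-2.00 ± 0.23), Dnah8 (-1.35 ± 0.15), Pisd-ps3 (-1.30 ± 0.15) and Glo1 (-0.90 ± 0.10) each had an adjusted p = 0.00216, and Cirbp changed by -0.84 ± 0.14 (adjusted p = 0.0445). Ighg3 (-1.84 ± 0.30) and 1700097N02Rik (-1.01 ± 0.16) also passed; they lie outside the naming rule and were named after their values were seen. In 7 of the 8 genes with another probe set, at least 1 such set differed the same way (limma, unadjusted p under 0.05). The exception was Ighg3, whose other probe sets lay higher in the knockout. They differed by 1.35 ± 0.44 (limma, unadjusted p = 0.00947) and 0.68 ± 0.32, so the direction of Ighg3 depends on the probe set. Among the ranked genes, all but Cirbp passed in each of the 10 fits that left out 1 array, and Cirbp passed in 2 of them. Without 4-month wild-type array 2 the 13 genes became 21. With the granulocyte and B cell scores as covariates limma called 0, with 223 at an unadjusted p under 0.05 against 757 in the main setting. The 223 lie below the 588 expected where no gene differs.

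**Figure D1:**
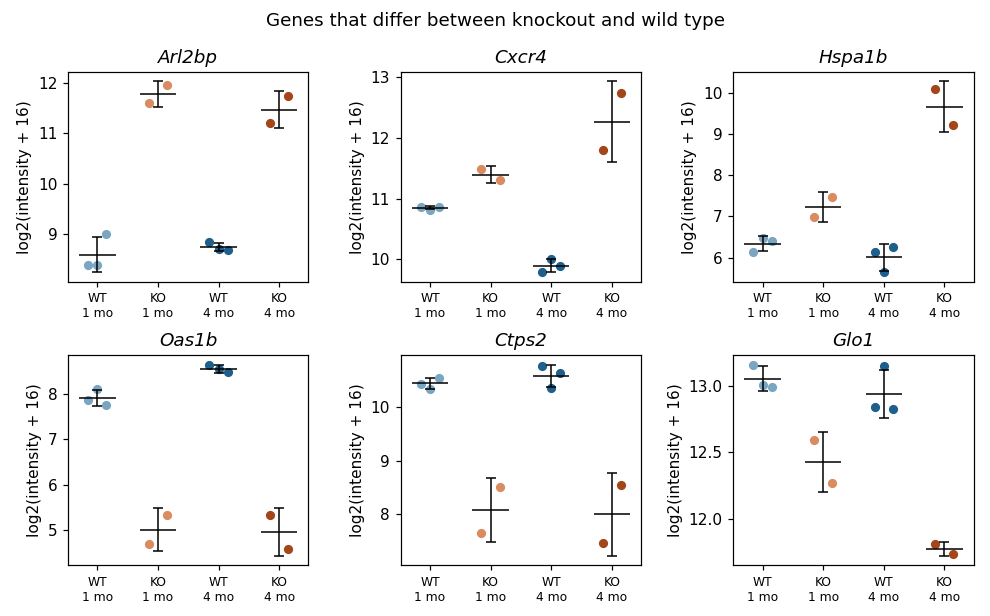
Log2 intensity of 6 genes in each group, with 1 point per array, a line at the mean and a bar of 1 SD. Arl2bp averaged 11.78 and 11.48 in the knockout at 1 and 4 months against 8.59 and 8.74 in wild type, and Oas1b 5.01 and 4.96 against 7.91 and 8.56.

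Lists in the mean of both ages followed the ages unequally. Granulocyte markers had a median of 1.23 with 25 of 25 positive and 5 higher when adjusted over the list alone (camera adjusted p = 2.32e-14; adjusted p = 0.44 with an estimated correlation). B cell markers had a median of -0.62 and 1 of 21 lower when adjusted over the list alone (camera adjusted p = 6.88e-07; adjusted p = 0.7 with an estimated correlation). Heat shock genes had a median of 0.16, with 1 of 26 risen and 5 higher when adjusted over the list alone (camera adjusted p = 5.33e-06; adjusted p = 0.44 with an estimated correlation). Medians of the other lists called were 0.13 for ribosomal, 0.06 for oxidative phosphorylation, 0.19 for plasma cell and 0.08 for glycolysis genes, and -0.22 for Treg, -0.50 for CD8 T and NK cell, -0.25 for Th1 and -0.32 for NF-kB genes (adjusted p = 0.7 with an estimated correlation). When adjusted over the list alone, 4 Th1, 3 CD8 T and NK cell, 1 NF-kB and 1 plasma cell gene passed, and of the lists not called 2 immediate early genes and 1 gene each of the effector memory, interferon, chemokine receptor, platelet and dendritic cell lists. The 11 lists became 8 without 1-month knockout array 1, 6 higher and 2 lower, of which 6 were among the 11. The means of NF-kB (-0.05, from -0.27), Th1 (-0.12, from -0.32), Treg (-0.11, from -0.26), CD8 T and NK cell genes (-0.23, from -0.45) and oxidative phosphorylation genes (0.06) then did not pass. The ribosomal mean became 0.03 (from 0.12) and that of glycolysis 0.02 (from 0.09) without 1-month knockout array 2. Without 4-month wild-type array 2 the 11 lists became 17. The lists that camera called in none of the 6 contrasts had, in the mean of both ages, medians of 0.05 for the IL-1 family, -0.13 for Th2, 0.01 for bone and joint mediators, 0.07 for platelet and -0.06 for stroma genes; the means of the bone and joint list (-0.01) and the platelet list (-0.03) had the opposite sign to their medians, and the tests of the platelet and stroma lists pointed upward.

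**Figure D2:**
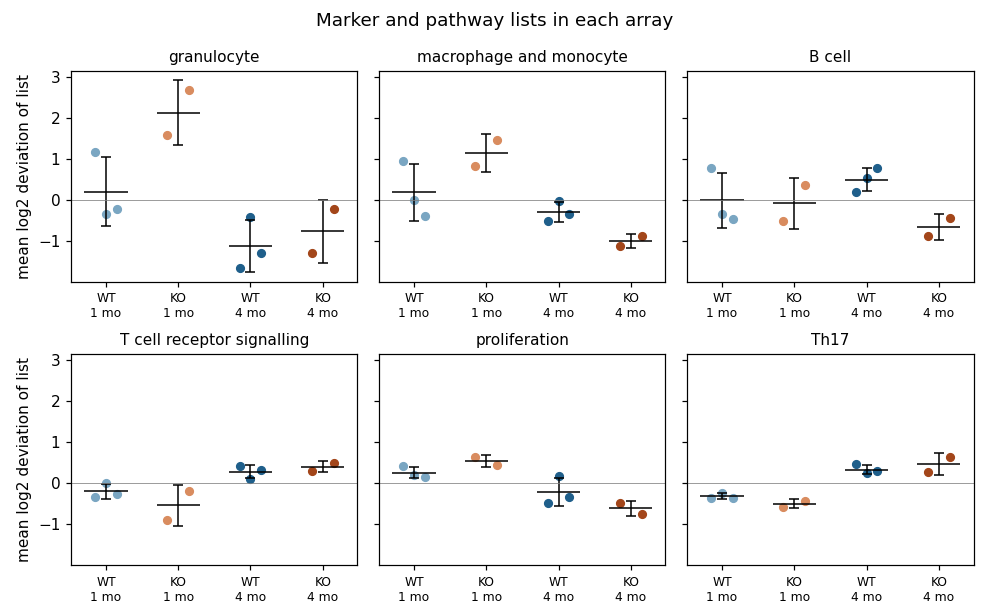
Mean log2 deviation of the genes of 6 lists from their mean over all arrays, with 1 point per array, a line at the group mean and a bar of 1 SD. The granulocyte score averaged 2.14 in the knockout and 0.21 in wild type at 1 month, and -0.76 and -1.12 at 4 months.

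In wild type, 788 genes were higher and 1186 lower at 4 than at 1 month, and 535 of the 1974 differed at least 2-fold. The balance turned with the choice of probe set: the mean of a gene's probe sets gave 1252 higher and 962 lower genes. Every probe set taken alone gave 4363 higher and 2353 lower probe sets, of which 1697 higher and 91 lower ones had no gene name. The long noncoding RNA Kcnq1ot1 rose by 3.72 ± 0.22, or 13.2-fold (adjusted p = 8.52e-06), with all 4 of its other probe sets past the test in the same direction, and the noncoding Lncpint rose by 3.65 ± 0.34 (adjusted p = 0.000104). Kantr rose by 4.11 ± 0.49 and Tbc1d1 by 3.04 ± 0.30, but their other probe sets differed by 0.43 to 1.20 and 0.33 to 0.49, and St6galnac3 (3.56 ± 0.33) had another probe set at -0.26. Without 4-month wild-type array 2 the change of Kantr was 0.40, and without array 1 that of Tbc1d1 0.30. Each such fit chose the probe set of a gene anew, and both values lie close to those of the other probe sets. These drops, and the counts of fits passed given below, can therefore reflect the probe set rather than the array. Phxr4 rose by 3.75, Slc9a8 by 2.88, Rab20 by 2.87, Tmem86b by 2.80 and the NK receptor gene Klrk1 by 2.79 ± 0.47. The 2 other probe sets of Slc9a8 differed by 0.77 to 0.93, and its change was 0.83 without 4-month wild-type array 1 and 0.92 without array 2. Both of these changes lie in the range of its other probe sets, so they too can come from a new choice of probe set. Genes of granule proteins fell: Elane changed by -3.48 ± 0.53, Mpo by -3.11 ± 0.46, Prtn3 by -2.74 ± 0.48, Ctsg by -2.67 ± 0.42 and Prg2 by -2.34 ± 0.48 (adjusted p = 0.00173 to 0.00874). Epdr1 (-4.43), Apol11b (-2.54), F13a1 (-2.33), the interferon-induced Rsad2 (-2.28) and Met (-2.13) also fell. Lncpint, Phxr4, Rab20, Tmem86b and Klrk1 were near the floor at 1 month and Epdr1, Apol11b and Met at 4 months, so their sizes depend on the pseudocount: at 1 and 64 Lncpint changed by 5.29 and 2.20, Rab20 by 4.31 and 1.71 and Met by -4.25 and -0.98. Of the 10 fits that left out 1 array, Kantr and Tbc1d1 passed in 5, Rsad2 in 6, Apol11b in 7, Slc9a8 in 8, Met in 9 and the other genes named above in 10. The 1974 genes became 976 without 1-month wild-type array 1, 629 without 4-month wild-type array 1 and 583 without 4-month wild-type array 3, and array weights gave 4158. With the granulocyte score as a covariate 330 genes passed. With the B cell score beside it limma called 0, with 361 at an unadjusted p under 0.05, below the 588 expected where no gene differs.

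Several lists of T cell genes lay higher at 4 months in wild type. Of 15 Th1 genes, 9 rose, 1 fell and 5 did not pass, with a median of 0.83 (camera adjusted p = 2.24e-05; adjusted p = 0.65 with an estimated correlation) and 12 past when adjusted over the list alone; Cxcr6 rose by 2.06 ± 0.19 and the interleukin-18 receptor gene Il18r1 by 2.30 ± 0.37. Of 29 effector memory genes, 15 rose, 1 fell and 13 did not pass, with 19 past when adjusted over the list alone (adjusted p = 0.65 with an estimated correlation); Ahnak rose by 2.16 ± 0.24 and S100a4 by 2.05 ± 0.21. Of 27 T cell receptor genes 8 rose and 1 fell, of 15 CD8 T and NK cell genes 7 rose, of 14 Th17 genes 5 rose, among them Ccr6 by 1.81 ± 0.23, and of 21 NF-kB genes 4 rose, among them Traf1 by 2.67 ± 0.19. Of 22 chemokine receptor genes 9 rose and 2 fell, of 22 Treg genes 4 rose, of 18 naive T cell genes 4 rose and of 21 B cell genes 2 rose and 1 fell. Each of these 8 lists had an adjusted p = 0.65 with an estimated correlation. Of the naive genes 12 were positive and 6 negative, and the list did not pass without 1-month wild-type array 1 (mean 0.16 against 0.31) or without 4-month wild-type array 1 or 3 (0.24 and 0.27). Camera did not call Tfh, where 1 of 15 genes rose (adjusted p = 0.0668), or Th2, where 1 of 7 rose (adjusted p = 0.0741). When adjusted over the list alone, 12 T cell receptor, 8 CD8 T and NK cell, 7 Th17, 7 NF-kB, 11 chemokine receptor, 8 Treg, 4 naive and 3 B cell genes passed.

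Of 37 proliferation genes in wild type, 1 rose (Tyms, by 1.36), 12 fell and 24 did not pass, with 19 past when adjusted over the list alone (adjusted p = 0.65 with an estimated correlation); the spindle motor gene Kif11 changed by -1.25 ± 0.25 and Ccne1 by -1.11 ± 0.22. Of 25 granulocyte genes 6 fell, with a median of -1.58 and 6 past when adjusted over the list alone, and of 25 erythroid genes 3 fell, with a median of -0.66 and 3 past when adjusted over the list alone (adjusted p = 0.65 with an estimated correlation for both). Of 49 oxidative phosphorylation genes 4 fell with a median of -0.15, and of 36 ribosomal genes 2 rose and 1 fell with a median of 0.23; with quantile normalization the test of the former turned its direction, and the mean of the latter was -0.04 (adjusted p = 0.65 with an estimated correlation for both). When adjusted over the list alone, 2 oxidative phosphorylation genes and 1 ribosomal gene passed. With an estimated correlation 0 of the 15 lists that camera called held, 0 lists had an unadjusted p under 0.05, and fry called 0 with 9 at an unadjusted p under 0.05. Quantile normalization moved the median of all genes from -0.035 to -0.16 in wild type and from -0.024 to -0.179 in the knockout, so small changes with age are relative to that shift.

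In the knockout, 1377 genes were higher and 1895 lower at 4 than at 1 month, and 1610 of the 3272 differed at least 2-fold. The mean of a gene's probe sets gave 1866 higher and 1677 lower genes, so here too the balance turned. Every probe set taken alone gave 5411 higher and 3190 lower probe sets, of which 1781 higher and 128 lower ones had no gene name. Neutrophil and macrophage genes had the largest falls: S100a9 changed by -5.33 ± 1.43 (adjusted p = 0.0168), Camp by -5 ± 1.20, Chil3 by -4.99 ± 1.25, S100a8 by -4.97 ± 1.34, Lyz1 by -4.97 ± 0.91, Elane by -4.80 ± 0.65, Ngp by -4.79 ± 1.40 and Hp by -4.31 ± 0.65. With 1 array left out in turn the change ranged from -7.47 to -3.20 for S100a9 and from -6.87 to -3.06 for S100a8. Csf1r, the receptor of the macrophage growth factor M-CSF, changed by -4.35 ± 0.42, or 20.4-fold (adjusted p = 0.000121), and Mpeg1 by -4.57 ± 0.53. Kcnq1ot1 rose by 3.84 ± 0.26 (adjusted p = 2.89e-05), Kantr by 4.69, Phxr4 by 4.16, Tbc1d1 by 3.74, Ighg3 by 3.45, Sfrp2 by 3.43, Lncpint by 3.40, Abi3bp by 3.38, Dis3l2 by 3.28 and Tmie by 3.27. Lncpint, Phxr4, Sfrp2, Abi3bp, Tmie, Kantr and Dis3l2 were near the floor at 1 month and Mpeg1, Chil3 and Hp at 4 months, so their sizes depend on the pseudocount: at 1 and 64 Abi3bp changed by 6.01 and 1.82, Lncpint by 5.13 and 1.97 and Sfrp2 by 4.61 and 2.20. The other probe sets of Kantr differed by 0.35 to 0.62, those of Ighg3 by 0.50 to 0.90 and that of Dis3l2 by 0.17, and those of Tbc1d1 by 0.65 to 0.88. Without 4-month knockout array 1 the change of Kantr was 0.59 and that of Tbc1d1 0.57. Probe sets were chosen anew in that fit, and these values lie near those of the other probe sets of both genes. For Kantr and Tbc1d1, these drops and the counts of fits passed that follow can therefore reflect the probe set rather than the array. Of the 10 fits that left out 1 array, Kantr passed in 5, S100a9, S100a8 and Ngp in 7, Camp, Chil3 and Tbc1d1 in 8, Tmie in 9 and the other genes named above in 10. The 3272 genes became 1463 without 1-month knockout array 1, 1717 without 4-month knockout array 1 and 1153 without 4-month knockout array 2. With the granulocyte score as a covariate 2 genes passed. With the B cell score beside it limma called 0, with 476 at an unadjusted p under 0.05, below the 588 expected where no gene differs.

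Proliferation genes fell with age in the knockout: 31 of 37 fell, 1 rose and 5 did not pass, with a median of -1.33 (camera adjusted p = 4.93e-10; adjusted p = 0.49 with an estimated correlation) and 32 past when adjusted over the list alone. Ccnb2 changed by -1.84 ± 0.26 and Tacc3 by -1.79 ± 0.25. Of 49 oxidative phosphorylation genes 25 fell and 24 did not pass, with a median of -0.48, 31 past when adjusted over the list alone and Ndufb2 at -1.12 ± 0.17 (adjusted p = 0.49 for the list with an estimated correlation). Of 25 granulocyte genes 17 fell with a median of -3.46, of 23 macrophage genes 15 fell with a median of -2.30, of 25 erythroid genes 19 fell with a median of -1.43 and of 9 mast cell genes 5 fell with a median of -1.41. Each of these 4 lists had an adjusted p = 0.49 with an estimated correlation. When adjusted over the list alone, 20 granulocyte, 19 macrophage, 20 erythroid and 5 mast cell genes passed. Tyrobp changed by -3 ± 0.41, Hemgn, an erythroid nuclear protein, by -2.09 ± 0.38, and the receptor gene Kit by -1.66 ± 0.21.

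T cell receptor genes rose with age in the knockout: 22 of 27 rose and 5 did not pass, with a median of 0.98 (camera adjusted p = 2.09e-08; adjusted p = 0.49 with an estimated correlation) and 25 past when adjusted over the list alone. Cd28 rose by 1.47 ± 0.16 and Plcg1 by 1.54 ± 0.21. Of 14 Th17 genes 8 rose, among them Il6ra by 1.71 ± 0.29, of 18 naive T cell genes 11 rose, of 15 Tfh genes 5 rose, and of 21 NF-kB genes 9 rose, among them Traf1 by 2.96 ± 0.23 and Socs3 by 2.20 ± 0.36 (adjusted p = 0.49 to 0.53 for these lists with an estimated correlation). Of 22 chemokine receptor genes 10 rose and 3 fell, of 29 effector memory genes 10 rose and 2 fell, of 22 Treg genes 8 rose and 1 fell, of 15 Th1 genes 5 rose and 1 fell, of 30 immediate early genes 8 rose and 2 fell, and of 34 interferon response genes 8 rose and 2 fell (adjusted p = 0.55 to 0.56 with an estimated correlation). When adjusted over the list alone, 11 Th17, 11 naive, 9 Tfh, 10 NF-kB, 17 chemokine receptor, 15 effector memory, 10 Treg, 6 Th1, 13 immediate early and 11 interferon response genes passed. Of the 17 lists called, 0 held with an estimated correlation and 1 list had an unadjusted p under 0.05, while fry called 10. Without 1-month knockout array 1 the Th1, effector memory, immediate early and interferon lists did not pass (means 0.21, 0.15, 0.20 and 0.07). Marker lists of granulocytes, macrophages and erythroid cells moved in the same comparison as the T cell lists, as their medians show.

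The age differences of the 2 genotypes, which rest on separate arrays, were compared across genes. Across genes, which are not independent replicates, they correlated with r = 0.71 (rho = 0.687). Of the genes past the test in both, 599 were higher in both against 92.3 for independent lists, and 854 were lower in both against 191. Both comparisons share 1 estimate of the spread per gene, so genes of small spread can pass in both and the lists are not independent. Any difference in handling between the ages would also move both genotypes alike. In contrast, the knockout differences at 1 and 4 months had r = -0.0557 (rho = -0.127), and Arl2bp was the gene higher at both ages, with Oas1b and Ctps2 lower at both.

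**Figure D3:**
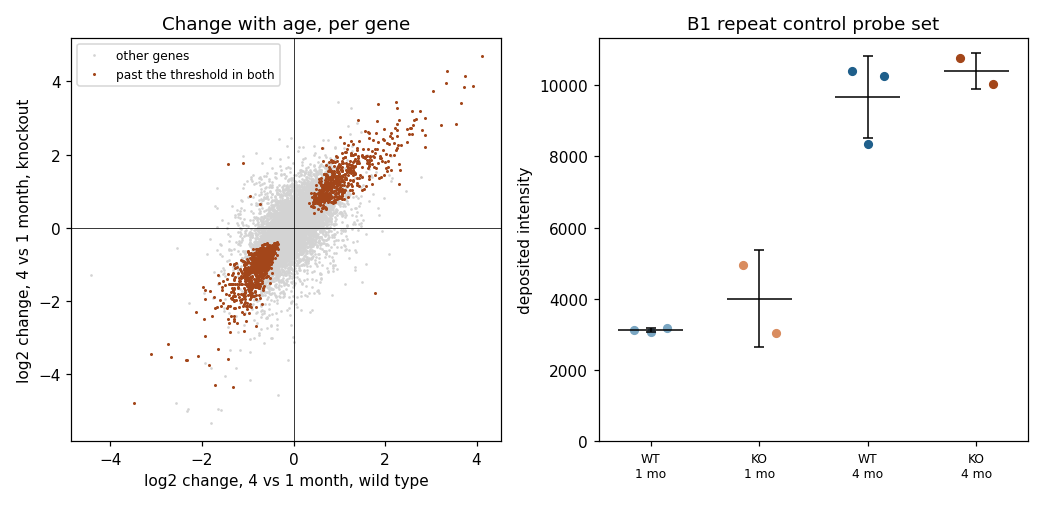
Left, log2 change from 1 to 4 months in the knockout against that in wild type, 1 point per gene. Right, intensity of the B1 repeat control probe set per array, which read 3035 to 4958 at 1 month and 8343 to 10772 at 4 months.

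The interaction asked whether the knockout difference changed with age. Plac8, which is expressed in several blood cell types, passed at -1.87 ± 0.24 (adjusted p = 0.0463): its log2 level was 13.12 in the knockout and 12.00 in wild type at 1 month, and 10.42 and 11.17 at 4 months. Genes of large difference that did not pass were Hspa1b (2.75 ± 0.49), Clec2d (2.87 ± 0.53), Cxcr4 (1.82 ± 0.31), Itpr2 (1.55 ± 0.29) and Irgm2 (1.39 ± 0.28), and with the opposite sign Mpeg1 (-4.22 ± 0.69), Ly86 (-3.15 ± 0.46), Csf1r (-3.03 ± 0.54) and Alox5ap (-2.58 ± 0.43), with adjusted p = 0.106 to 0.24. Plac8 passed in 2 of the 10 fits that left out 1 array, those without 1-month wild-type array 1 (8 genes) and array 2 (2 genes). Without 1-month knockout array 1 or array 2, 4-month knockout array 2, or 4-month wild-type array 1 or array 3, limma called 0 with 788 to 1588 genes at an unadjusted p under 0.05. Without 4-month knockout array 1, 1-month wild-type array 3 or 4-month wild-type array 2 it called 1 other gene and not Plac8.

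Camera called 14 lists in the interaction. Macrophage genes had a median of -1.48 with 9 of 23 lower when adjusted over the list alone (camera adjusted p = 9.22e-11), proliferation genes -0.76 with 8 of 37 past when adjusted over the list alone (adjusted p = 9.22e-11) and B cell genes -1.01 with 5 of 21 (adjusted p = 1.56e-05). Each had an adjusted p = 0.43 with an estimated correlation. T cell receptor genes had a median of 0.48 with 27 of 27 positive and 1 higher when adjusted over the list alone (adjusted p = 9.82e-06; adjusted p = 0.43 with an estimated correlation). Without 1-month knockout array 1 camera called 1 of the 5 higher lists, Tfh, and the T cell receptor mean became 0.12 (adjusted p = 0.109). Tacc3 differed by -1.26 ± 0.32, Tyrobp by -2.99 ± 0.54 and Cd28 by 0.81 ± 0.20 without passing (adjusted p = 0.362, 0.172 and 0.349). Of the 14, 0 held with an estimated correlation (adjusted p = 0.43), 1 list had an unadjusted p under 0.05, and fry called 0 with 5 at an unadjusted p under 0.05.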

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

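Among the tests given here, those on the 13 genotype genes were chosen after the result was seen, except the covariate test on calls, and so were the split of the dim-range test by class of probe set, the repeat of the test on higher genes after quantile normalization, the test of how much of the age change remains with the granulocyte score and all 3 tests on granulocyte markers. The covariate tests on calls were set before their own results, but the fits with marker scores were themselves added after the data were seen.

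The knockout difference changed between the ages in limma for Plac8, by -1.87. Camera found the difference to change in 14 lists. The interaction medians were -1.66 for granulocyte, -1.48 for macrophage, -1.04 for mast cell, -1.01 for B cell, -0.96 for CD8 T and NK cell, -0.78 for erythroid, -0.76 for proliferation, -0.31 for oxidative phosphorylation and -0.19 for dendritic cell genes. They were 0.65 for Tfh, 0.55 for naive T cell, 0.53 for immediate early, 0.48 for T cell receptor and 0.41 for interferon response genes. With an estimated correlation camera called 0 of these 14, with 1 list at an unadjusted p under 0.05, and fry called 0 with 5. Without 1-month knockout array 1 camera called 1 of the 5 lists of positive median, Tfh. Plac8 passed in 2 of the 10 fits that left out 1 array, those without 1-month wild-type array 1 or 2. Without 1-month knockout array 1 or 2, 4-month knockout array 2, or 4-month wild-type array 1 or 3, limma called 0 genes, with 1038, 1588, 788, 1135 and 905 at an unadjusted p under 0.05. Without 4-month knockout array 1, 1-month wild-type array 3 or 4-month wild-type array 2 it called 1 other gene and not Plac8.

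Probe sets outside the gene tests also differed with age. The control for B1 repeats, short repeats found in many introns, was 1.54 higher in log2 at 4 months, or 2.91-fold (exact permutation test of 5 against 5 arrays, two-sided p = 0.00794, the smallest it can give). Among probe sets with no gene name, 1697 were higher and 91 lower at 4 months in wild type, and 1781 were higher and 128 lower in the knockout.

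Of the 13 genotype genes, 7 of the 8 with several probe sets had another that differed the same way (limma, unadjusted p under 0.05). In Ighg3 another went the other way (1.35 ± 0.44). For the 7 genes the agreement argues against a mismatch of a single probe to 1 strain, but less so for Sfi1 and Pisd-ps3. Their agreeing other probe sets were all of the kind that can bind several transcripts, and another of Pisd-ps3 differed by -0.15 ± 0.35. For the 5 genes with 1 kept probe set a mismatch cannot be told apart. The only other probe set, of Dnah8, lay above the median in 0 arrays and was removed by the filter (-0.39 ± 0.35). Of 100 splits of the arrays within age, the real one included, 2 gave at least the real 13 genes, a share under 0.05. These were the real split itself and 1 other, which gave 17. With granulocyte and B cell scores as covariates limma called 0 of the 13, since the median standard error rose from 0.16 to 0.59. All 13 kept their direction and most of their change, with a median size of 1.55 against 1.84. For Arl2bp, Ctps2, Glo1, Hspa1b, Oas1a and Oas1b this argues against the makeup of these cells as the whole cause (limma, unadjusted p = 0.0012 to 0.0096). For the other genes the standard errors were too wide to decide, as for Cirbp (-0.66 ± 0.52) and Cxcr4 (0.79 ± 0.53). Among the 13 were 4 pairs at most 5 genes apart in the gene order of GRCm38.p6. They came from the neighbours 1700097N02Rik, Dnah8 and Glo1 and the pair Oas1a and Oas1b. In 10000 random draws of genes there were at most 2 (permutation p = 1e-04, the smallest they can give). The distance was set after the pairs were noticed. The draws took single genes, whereas Oas1a and Oas1b are of the same family and the other pairs share a single cluster. This p can therefore overstate the evidence for strain segments. A candidate explanation is chromosome segments from another strain background that differ between the mouse lines, which stays open beside an effect of the missing antagonist because the labels give no strain.

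With the granulocyte score as a covariate, 314 of the 1974 genes that differed with age in wild type passed, while the median standard error rose from 0.18 to 0.25, all 1974 kept their sign and the lower quartile of the share of its change that a gene kept was 0.887; in the knockout 2 of 3272 passed, with a lower quartile of 0.673. This argues against granulocytes as the whole cause in wild type. A shift of the dim range as the whole cause is argued against by the gap in the share of higher probe sets between those that are not the brightest of a gene, unnamed ones included, and the brightest, which was 35.8 percentage points and stayed at 28.8 after quantile normalization; for other probe sets of named genes alone it fell from 24.6 to 13.8, so the scaling accounts for part of it. More unspliced or repeat-containing RNA at 4 months is a candidate explanation for genes whose probe sets moved apart. The dimmer probe sets were the higher ones in 92.0% of 176 such genes (exact 95% interval 87.0% to 95.6%). A rise of the dim range at 4 months would give this as well, and the test was not repeated after quantile normalization. It therefore cannot tell these explanations apart. For the higher genes as a whole, unspliced or repeat-containing RNA cannot be told apart either. The share with another probe set moving the same way was 3.04 points greater than among lower genes (95% interval -1.44 to 7.53). After quantile normalization the difference was -11.7 points (-16.3 to -7.24), so its sign turns with the scaling. The 10 splits of the wild-type arrays, the real one included, are too few for a share under 0.05. The real split gave 1974 genes and the highest other gave 0. Any difference in handling between the ages coincides with age, as does the 3' to 5' ratio of Gapdh. The labels give no batch, and age itself stays open, untested.

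The granulocyte markers that lay higher in the knockout at 1 month varied together within groups. Their median correlation of residuals was 0.458 against 0.0964 at percentile 95 of random lists. B cell markers, which differed by -0.07, correlated at 0.809, so such a correlation cannot show that the genotypes differ. Granulocytes in the preparation are a candidate source. Selection for CD4 would remove them, and its purity is not given. S100a9 read 15218 and 32497 in the knockout arrays and 12233, 645 and 1449 in wild type, and Lyz2 read 2853 and 7123 against 2755, 607 and 647; of the 25 markers, 5 are also in another list. Granulocyte markers differed by 1.93 with all arrays (95% interval over arrays 0.25 to 3.61). A lower share of T cells alone is argued against by B cell markers, which differed by -0.07. The gap was 2 with a standard error over arrays of 0.37 (95% interval 1.08 to 2.91). A single knockout array as the source cannot be told apart: the mean change was 2.48 without array 1 but 1.38 without array 2, with a 95% interval over arrays of -0.84 to 3.59, since 1 knockout array of that age is then left. The scores of the arrays gave an exact two-sided permutation p = 0.2, where 10 splits cannot give a p under 0.1, and an effect of the genotype on these cells stays open, untested.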

How the results depend on the processing

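The fits with marker scores as covariates and the fit without 2 arrays were chosen after seeing the data; the other alternatives were planned. Of 2084 comparisons of 85 named-gene results with an alternative, 1761 kept direction and side of the threshold, 289 fell short of it, 19 newly passed and 15 reversed. The 15 came from fits with marker scores as covariates, and all but those of Epdr1 and Lyz1 were of members of the granulocyte score. Of 1637 for 87 list results, 1286 kept both, 318 fell short and 33 reversed. Among the gene comparisons, those with values as deposited could only agree, since scaling left the arrays as deposited. Values below are genes past the threshold in limma, or list means in log2, and the cause was not tested unless given.

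Array weights gave 3 genes at 1 month, 192 at 4 months, 4158 for age in wild type and 0 for the interaction (1045 at an unadjusted p under 0.05). Testing every probe set counts a gene more than once and adds the unnamed probe sets and those with several genes. It gave 38 probe sets at 1 month, 30 at 4 months and 43 in the mean of both ages. For age it gave 6716 in wild type and 8601 in the knockout. The balance of directions with age turned with the choice of probe set. With the mean of probe sets, wild type gave 1252 higher and 962 lower genes and the knockout 1866 and 1677. With every probe set, wild type gave 4363 higher and 2353 lower probe sets and the knockout 5411 and 3190. Probe sets with no gene name made up 1697 higher and 91 lower of these in wild type, and 1781 and 128 in the knockout. Fitting only the 2 groups compared gave 74 at 4 months. The interaction gave 0 with a pseudocount of 1 (1183 at an unadjusted p under 0.05), no intensity trend (1081), the mean of probe sets (1135) and the replicate block (1159). That block pairs arrays that share only a number, and of 13 such pairs 3 had a residual correlation over 0.1 (range -0.14 to 0.28), so the arrays were not paired. With the block the counts of genes were 7, 7, 11, 1901, 3220 and 0 in the order of the contrasts. Without 1-month knockout array 1 and wild-type array 1 there were 29 genes at 4 months, 1466 for age in the knockout and 30 for the interaction.

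With the granulocyte score as a covariate 1, 29 and 8 genes passed at 1 month, at 4 months and in the mean. For age in wild type and knockout 330 and 2 passed. For the interaction 0 passed, with 423 at an unadjusted p under 0.05, below the 588 expected where no gene differs. Reversed list means were -0.06 for heat shock, -0.11 for macrophage and -0.18 for erythroid genes at 1 month, and -0.12 for plasma cell genes in the mean. Reversed in the knockout's age change were S100a9 (1.92), Camp (1.34), Chil3 (0.65), S100a8 (1.74) and Ngp (2.52), all 5 of them members of the score itself. A list's own score was not used to test that list.

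With the granulocyte and B cell scores as covariates limma called 0 genes in all 6 contrasts. At an unadjusted p under 0.05 there were 185, 312, 223, 361, 476 and 359, all below the 588 expected where no gene differs. Camera called 5 lists at 1 month, 10 at 4 months, 2 in the mean, 6 for age in wild type, 11 in the knockout and 16 for the interaction. Of these, 4, 3, 0, 5, 8 and 10 were among the lists called without covariates. Reversed at 1 month were the means or tests of Treg (0.00), NF-kB (0.02), interferon (-0.10), proliferation (-0.34), heat shock (-0.04) and erythroid (-0.50). At 4 months these were Th1 (-0.03), effector memory (0.09), ribosomal (-0.01) and mast cell (0.20), and in the mean Th1 (-0.01), Treg (0.17), NF-kB (0.27), oxidative phosphorylation (-0.08) and plasma cell (-0.21). For age in wild type they were Treg (-0.05), naive (-0.08), NF-kB (-0.07), proliferation (0.12), oxidative phosphorylation (-0.02) and erythroid (-0.04). Among genes, Epdr1 (1.48), Elane (0.30), Mpo (0.10), Prtn3 (0.89) and Ctsg (0.88) reversed in wild type. In the knockout S100a9 (2.83), Camp (1.56), Lyz1 (0.15), S100a8 (3.35) and Ngp (4.15) reversed. All of these genes but Epdr1 and Lyz1 are members of the granulocyte score itself. The 2 scores leave 4 residual degrees of freedom, and the standard errors rose.

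With quantile normalization the ribosomal mean for age in wild type reversed from 0.18 to -0.04. The oxidative phosphorylation mean kept its sign (-0.08 from -0.17) and only the direction of its test reversed, short of the threshold. With an estimated correlation camera called 0 lists in all 6 contrasts, with 2, 2, 2, 0, 1 and 1 at an unadjusted p under 0.05. The test fry called 0, 0, 0, 0, 10 and 0 lists, with 3, 4, 2, 9, 14 and 5 at an unadjusted p under 0.05.

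Leaving out each array in turn, where a lone array of a group is assumed to vary like the others, gave 1 to 13 genes at 1 month, 4 to 14 at 4 months, 10 to 21 in the mean, 583 to 2396 for age in wild type, 1153 to 3892 in the knockout and 0 to 8 for the interaction. At 1 month 3 genes passed without knockout array 1, 1 without wild-type array 2, 1 without wild-type array 3 and 5 without 4-month wild-type array 3. At 4 months 4 passed without knockout array 1, 5 without knockout array 2 and 6 without wild-type array 1. In the mean 21 passed without 4-month wild-type array 2. For age, wild type gave 976 without 1-month array 1, 629 without 4-month array 1 and 583 without 4-month array 3, and the knockout 1463 without 1-month array 1, 1717 without 4-month array 1 and 1153 without 4-month array 2. The interaction gave 0 without 1-month knockout array 1 or 2, 4-month knockout array 2, or 4-month wild-type array 1 or 3 (1038, 1588, 788, 1135 and 905 at an unadjusted p under 0.05), 8 without 1-month wild-type array 1 and 2 without array 2. Plac8 was among the genes called in those last 2 fits alone.

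Lists past the threshold ranged from 8 to 16 at 1 month, with 8 without knockout array 1, all 8 higher and 0 lower, so the 7 lower lists rest on that array, and from 8 to 17 in the mean, with 8 without 1-month knockout array 1, where NF-kB (-0.05), Th1 (-0.12), Treg (-0.11), CD8 T and NK cell (-0.23) and oxidative phosphorylation genes (0.06) fell short, and 17 without 4-month wild-type array 2. List means at 1 month ranged from -0.86 to 0.02 for NF-kB, -0.70 to 0.00 for T cell receptor, -0.58 to 0.00 for immediate early and -0.08 to 0.41 for erythroid genes, each turned by leaving out knockout array 1, and from -0.02 to 0.33 for ribosomal genes, turned by knockout array 2. In the same fits the means ranged from -0.77 to -0.07 for naive, -0.75 to -0.06 for Tfh, -0.66 to -0.05 for Treg and -0.56 to -0.17 for interferon genes, each smallest and short of the threshold without knockout array 1. Without that array the interaction kept 1 of 5 higher lists, and naive (0.20), immediate early (0.09), interferon (0.15) and T cell receptor genes (0.12) fell short. The naive list for age in wild type, with a mean of 0.31, fell short without 1-month array 1 (0.16) and 4-month array 1 (0.24) or 3 (0.27). At 4 months the granulocyte mean ranged from -0.18 without knockout array 2 to 0.90, and T cell receptor (0.03), Tfh (0.03) and plasma cell genes (0.11) fell short without that array. Signal near the floor limits dim genes: Il1rn lay above the array median in at most 1 array on each of its probe sets.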
